A study of Arabidopsis thaliana with 8 samples.

How the data were processed

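Inflorescence stem RNA of 8 pooled samples of Arabidopsis thaliana was measured on 1-colour Affymetrix arrays after biotin labelling, per the labels' protocols. The deposited values were intensity values per probe set on a linear scale, from 6.62 to 19683. RMA is named in the submitters' processing notes, with no version. RMA gives log2 values, so the deposited intensity values appear to have been turned back to a linear scale. The chip definition, the arrays that entered RMA together and any filter are not given in the sources used here. RMA makes the quantiles of arrays nearly equal, so a shift of most transcripts in 1 direction would not be visible. The test design assumed log2 values, and log2 of the intensity was therefore taken first, with no pseudocount.

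Of 22810 probe sets, 64 were controls and were left out, leaving 22746 for all tests. No cutoff for detection was applied, and folds of dim probe sets are open to background. Where a named gene was not above the highest of the 3 TrpnX control probe sets (log2 3.30 to 3.93 over the arrays) in every array of a group, or in 1 of 2, its fold is given as a bound, with each array of that group at the higher of that level and its own value. This level was chosen after the data were seen. Gene names came from the platform annotation, with symbols and locus tags updated through the gene identifiers of a table for the TAIR10.1 assembly. In it 13513 probe sets (59.4%) had 1 gene, 503 had several and 8730 were not listed. Those not listed are unnamed here and were reported by probe set at most. Of the probe sets with 1 gene, 13436 matched the gene table, and 13355 genes were represented, each by the probe set with 1 gene only and the highest mean over all arrays. No coordinates are given because no build is stated with the values, and the gene table served for names and gene order only.

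Groups and replicate numbers came from the labels, which call the samples biological replicates with stems of 5 plants in each. The design text speaks of 3 replicates, and 2 fah-1 samples were analysed here. No pair of arrays held identical columns. Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all 22746 probe sets and a threshold of 0.05. Unless named otherwise, every p is limma's, from this moderated test. SEs are the moderated SEs of the log2 fold change, and SDs are between arrays of a group. limma was tested in 3 simulations with the spread of the real arrays. In all, 201 probe sets were changed at each of 1.5-fold, 2-fold and 4-fold. In F5H-OE against WT it recovered 65.7%, 93.0% and 99.5% of them, and 5.29% of its calls were false. In F5H-OE against fah-1 it recovered 49.8%, 88.6% and 99.0%.

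Before the data were examined, 26 lists with 421 genes of lignin and wall formation, related metabolism, stress, hormones and tissue markers were fixed, together with the tests, most alternatives and the rule for named genes. Of these genes 61 could be named, 6 lists had no named gene and 10 had at least 3, the minimum for a set test. The 6 were those of secondary wall transcription factors, primary wall cellulose synthases, the methyl cycle, xylem vessel, cambium and epidermis and cuticle. Set tests used limma camera with a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 10 lists within a comparison. The rule for named genes took, per comparison, the 10 named genes that rose most and the 10 that fell most among those past the threshold whose values did not overlap between the groups. With fewer than 5 such genes it took the 5 with the smallest p in each direction. Up to 4 members of each list with the smallest adjusted p were added. It also asked for F5H in every array, which could not be given because no probe set carried its name. 253088_at and QQS in F5H-OE were named after their values were seen.

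For the position of changed genes, named genes of chromosomes 1 to 5 were put in gene order and divided into windows of 250, after windows of 100 had been tried, and changed genes were shuffled over the genes 10000 times. Windows of 500 were run later as a check, with 4 dense windows. Alternatives were recentred or quantile normalized values, filters on dim probe sets, fits of 2 groups, a trended or robust spread, array weights, the replicate number as a block, and each array left out in turn. In fits that left 1 fah-1 array, that array was assumed to vary like the other groups.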

Results

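Transcript levels were measured in inflorescence stems of Arabidopsis thaliana plants, ecotype Columbia-0, at 1.5 months of age. The series concerns ferulate/coniferaldehyde 5-hydroxylase (F5H), the cytochrome P450 enzyme of the step towards syringyl lignin. The 8 arrays comprised 3 of wild-type (WT) stems, 3 of a line labelled as an F5H overexpressor (F5H-OE) and 2 of a line labelled as the F5H loss-of-function mutant fah-1. Each sample pooled stems from 5 plants. Median intensities were alike, from 112 in fah-1 replicate 1 to 118 in F5H-OE replicate 2, and the small number of arrays limited the precision. Mean within-group correlations of log2 values were 0.994 to 0.995 for the WT arrays and 0.997 for the pair of fah-1 arrays. F5H-OE replicate 1 stood apart, with a mean correlation of 0.987 with the other F5H-OE arrays, against 0.997 between replicates 2 and 3. The 3′ minus 5′ difference of the GAPDH control probe sets, a sign of RNA quality, was 1.47 on the log2 scale in F5H-OE replicate 1 and at most 0.853 in the other arrays. No probe set carried the name of F5H (AT4G36220) in the annotation used, so the level of the targeted transcript was not used to check the labels.

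The comparison of F5H-OE with WT asks what else differs in stems of a line in which F5H is overexpressed. GSTU25, a tau-class glutathione S-transferase, was at least 22.2-fold higher in F5H-OE, at an intensity of 314 ± 91.5 (SD, n = 3) against 13.1 ± 1.76 (SD, n = 3) in WT, where it was not above the level of the TrpnX control probe sets on any array. AT3G53980, a member of the lipid-transfer protein family, showed the largest fall, 17.2-fold, from 4146 ± 411 to 246 ± 63.4 (SD, n = 3 in each group). In all, 603 of 22746 probe sets changed at an adjusted p under 0.05, of which 293 were higher and 310 lower in F5H-OE. Among them were 319 named genes, 151 higher and 168 lower.

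Among the 10 named genes that rose most, AT1G02300, a cathepsin B-like protease, rose by 2.18 ± 0.096 (log2 fold change ± SE, adjusted p = 2.1e-05). The others were AT5G59845 of the GASA family at 2.33, AT5G42830 of the HXXXD acyltransferase family at 2.18, AT5G37980 of the alkenal reductase family at 1.94, AT2G07000 at 1.90, AT3G20340 at 1.89, CYTC6A, a cytochrome c6A, at 1.89, the F-box gene AT5G60610 at 1.85 and the methyltransferase gene AT2G41380 at 1.83. AT5G59845 and AT5G42830 varied most among the F5H-OE arrays, with SEs of 0.477 and 0.417 and adjusted p of 0.045 and 0.035. Both calls ended without any 1 WT array, without F5H-OE replicate 3, in a fit of these 2 groups alone and with a robust spread, and that of AT5G59845 also without F5H-OE replicate 2 (adjusted p over the alternatives 0.00012 to 0.140 for AT5G59845 and 0.00039 to 0.119 for AT5G42830). AT5G56380, an F-box gene, fell by 3.07 ± 0.083 (log2, SE, adjusted p = 4.5e-06), the smallest p among these 20 genes. The other log2 fold changes were -3.67 for AT5G51620, which lay at the TrpnX level in 1 of the 3 F5H-OE arrays, -2.84 for AT5G56910, -2.73 for AT5G58980 of the neutral ceramidase family, -2.65 and -2.61 for the berberine bridge enzyme-like genes AT1G30760 and AT5G44380, -2.57 for HRD, an AP2/ERF transcription factor, -2.53 for AT1G06640 of the 2-oxoglutarate oxygenase family and -2.52 for AT2G14880 of the SWIB domain family.

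**Figure D1:**
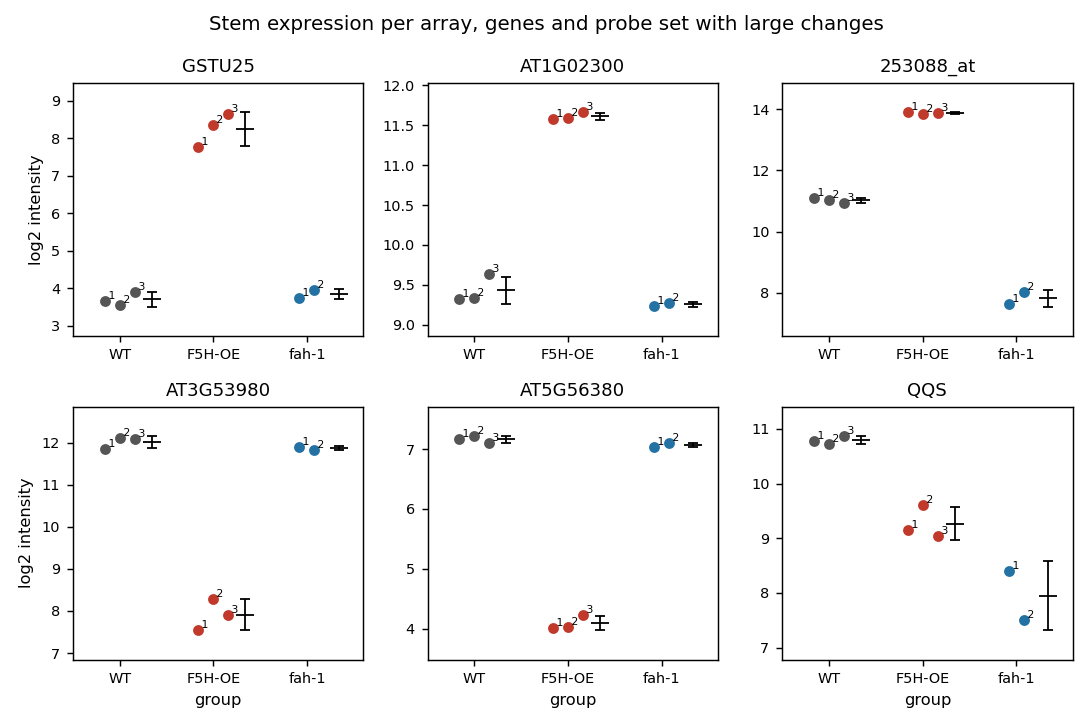
Log2 intensity (y axis) per array for 5 named genes and the probe set 253088_at in the 3 groups (x axis); numbers give the replicate, and the bar beside each group gives the mean and SD. GSTU25 and AT1G02300 were higher and AT3G53980 and AT5G56380 lower in all 3 F5H-OE arrays than in every WT and fah-1 array, and 253088_at moved in opposite directions in F5H-OE and fah-1.

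Changed genes lay unevenly along the chromosomes. Of 316 changed named genes with a place on the nuclear chromosomes, 126 were on chromosome 5, or 4.23% of its 2981 genes, against 1.03% on chromosome 4 and 1.32% on chromosome 3. In windows of 250 neighbouring genes, 7 of 54 windows held more changed genes than 14, the 95% point of the fullest window over 10000 shuffles. A run of 5 such windows covered chromosome 5 from AT5G38160 to AT5G62910, 1 lay on chromosome 1 from AT1G06420 to AT1G11700, and 1 on chromosome 2 from AT2G01060 to AT2G06090. These dense stretches held 132 changed genes, 57 higher and 75 lower, or 7.54% of their 1750 genes, against 1.60% elsewhere. Their ends rest on a count not scaled to window size. The last window of chromosome 5, from AT5G62930 to AT5G67630, held 14 of 231 genes (6.06%) and counts as elsewhere. The first window of the run held 15 of 250 (6%). On chromosome 1 the window before the dense one held 13 of 250 (5.2%). The share inside is raised by picking the windows on these same calls. With replicate 1, 2 or 3 of both groups left out, as many genes were taken by smallest p. The dense windows then numbered 3, 4 and 6, of which 3, 3 and 5 were among these 7. These fits reuse the other arrays, so the overlap is not independent, and 1226, 83 and 63 genes passed in them. In the main fit the fullest window held 27, above the 21 of the fullest window in any shuffle. Of the 20 genes named above, 10 lay inside the dense stretches, among them AT5G56380, AT5G51620, AT5G58980, AT5G44380, CYTC6A and AT1G06640, while GSTU25, AT3G53980, HRD and AT1G02300 lay outside. For genes at an unadjusted p under 0.05 in fah-1 against WT, the shares inside and outside were 4.17% and 4.58%. The window size was chosen after the data were seen, windows of 100 genes having been tried first. With these, 4 windows were dense, 3 of them on chromosome 5, and 11.8% of their genes had changed against 2.1% elsewhere.

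**Figure D2:**
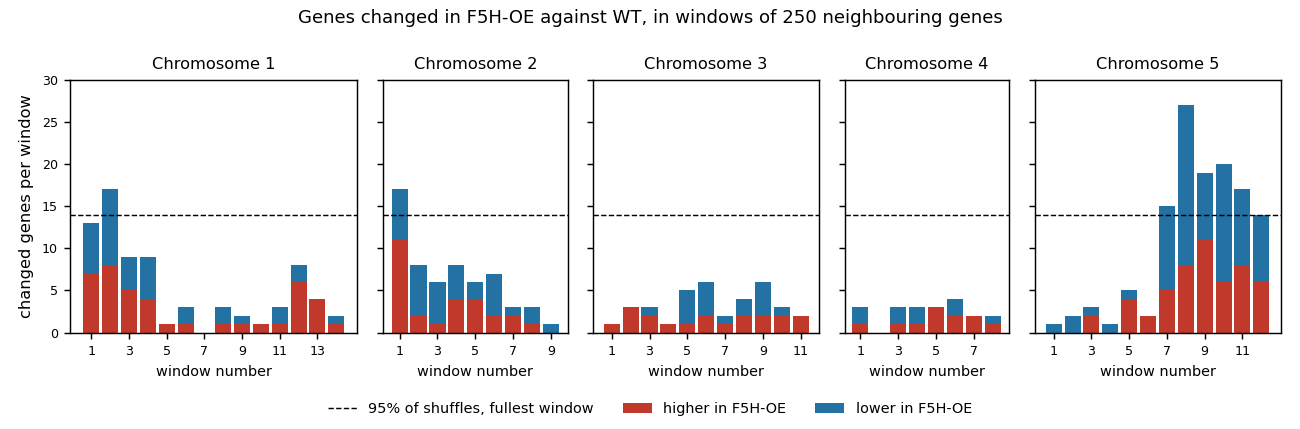
Number of named genes changed in F5H-OE against WT (y axis) in windows of 250 neighbouring genes along chromosomes 1 to 5 (x axis, windows in gene order); red and blue give the genes higher and lower in F5H-OE, and the dashed line marks 14, the 95% point of the fullest window over 10000 shuffles. The fullest window, on chromosome 5, held 27 changed genes.

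Of the 61 named genes on the fixed lists, 2 changed in F5H-OE against WT, both downwards. REF1, the aldehyde dehydrogenase that forms ferulic and sinapic acid, fell by 0.55 ± 0.10 (log2, SE, adjusted p = 0.032), from 1870 ± 89.3 to 1285 ± 139 (intensity, SD, n = 3 each). It was the 1 member to change of the 11 measured of sinapate esters and phenylpropanoid glucosides, over all genes as when adjusted over the list alone, and the glucosyltransferase UGT72E1 had a log2 fold change of -0.87 that did not pass (adjusted p = 0.140) but did with array weights and without WT replicate 1 (0.014 to 0.359 over the alternatives). The call of REF1 ended without any 1 WT array, without F5H-OE replicate 2 or 3 and in a fit of these 2 groups alone (adjusted p 0.018 to 0.108 over all alternatives). UGT75C1, an anthocyanin glucosyltransferase, fell by 0.71 ± 0.093 (log2, SE, adjusted p = 0.0072), again 1 of the 6 measured flavonoid and anthocyanin genes in both counts, and UGT78D1 had a log2 fold change of -0.40 (adjusted p = 0.381). The median log2 fold change was -0.14 over the sinapate list and -0.15 over the flavonoid list. camera gave the list an adjusted p of 0.248, or 0.648 with an estimated correlation, and fry, which asks whether the members move one way, an adjusted p of 0.044.

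No member of the wall lists passed over all genes in the main fit of F5H-OE against WT. Among the 4 measured lignin polymerisation genes, the peroxidase gene PRX72 passed when adjusted over the list alone, with a log2 fold change of 0.61 (adjusted p over all genes 0.087), while PRX71 stood at 0.63 and PRX25 at -0.62. PRX72 was dim, with log2 intensities of 3.78 to 4.33 in WT and 4.56 to 4.88 in F5H-OE, near the TrpnX level of up to 3.93. Both filters on dim probe sets left it out. PRX72 and PRX25 passed over all genes with array weights and without F5H-OE replicate 1, where PRX25 was at -0.99, and PRX72 also with values quantile normalized again (adjusted p over the alternatives 0.015 to 0.266 for PRX72 and 0.0097 to 0.582 for PRX25). The 3 measured secondary wall polysaccharide genes had a median log2 fold change of 0.10, with IRX10, of the xylan backbone, at 0.10. Of the monolignol pathway 2 of 18 genes could be named, HCT at 0.07 and CCR2, a cinnamoyl-CoA reductase, at 1.28 (adjusted p = 0.384). CCR2 had a log2 intensity of 8.68 in F5H-OE replicate 1, against 5.61 and 5.88 in replicates 2 and 3 and 5.40 to 5.51 in WT. The array that stood apart carried other list genes too: PRX71 was 2.04 and the touch-responsive CML38 2.50 higher there than the mean of the other F5H-OE arrays, while the difference was -1.51 for GH3.5, an auxin-responsive gene (log2). Without that array the log2 fold change from WT was -0.05 for PRX71, -0.07 for CML38 and 1.19 for GH3.5, which then passed, as with array weights (adjusted p over the alternatives 0.0056 to 0.694). SWEET11, a sucrose exporter of the phloem and the 1 measured phloem marker, had log2 intensities of 9.17 in F5H-OE replicate 1 and 5.88 and 6.50 in replicates 2 and 3, against a WT range of 8.29 to 9.84. Over all 3 arrays its log2 fold change of -1.90 did not pass (adjusted p = 0.256), and without F5H-OE replicate 1 it was -2.89 with an adjusted p of 0.0049 (0.0049 to 0.522 over the alternatives).

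**Figure D3:**
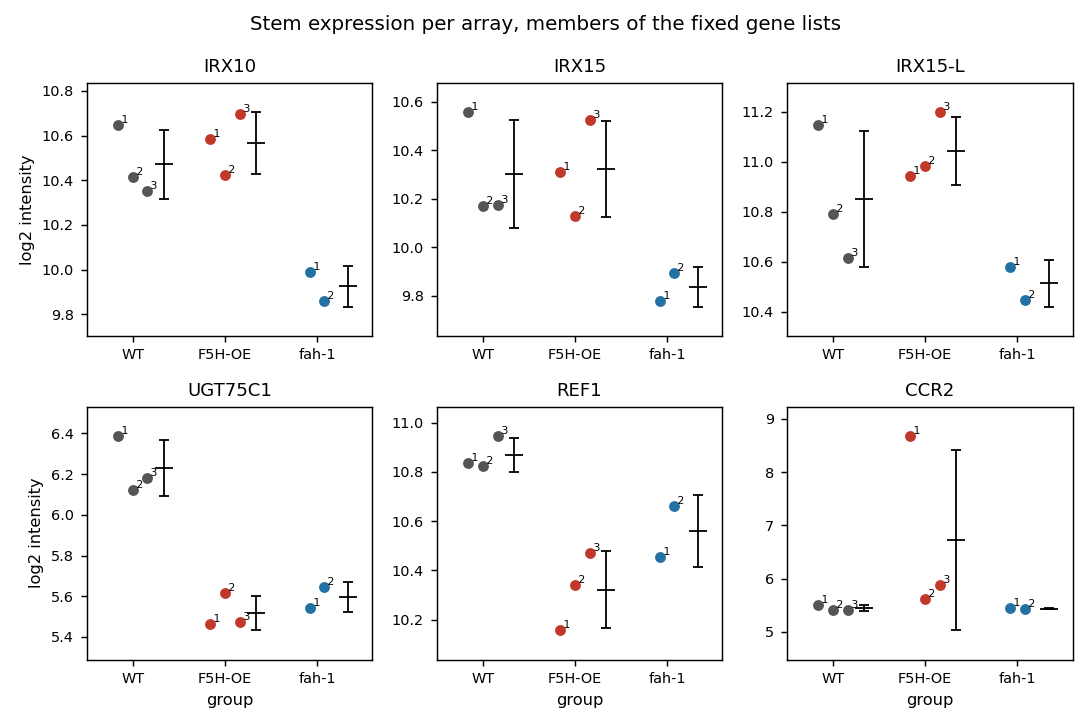
Log2 intensity (y axis) per array for 6 members of the fixed lists in the 3 groups (x axis); numbers give the replicate, and the bar beside each group gives the mean and SD. CCR2 was at 8.68 in F5H-OE replicate 1 and between 5.40 and 5.88 in the other 7 arrays.

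The 5 measured photosynthetic tissue markers had a median log2 fold change of 0.12 in F5H-OE against WT, and none passed. Median log2 fold changes in the other lists tested as sets were 0.12 over 3 jasmonate and ethylene defence genes, 0.03 over 4 aliphatic glucosinolate genes, 0.02 over 3 abscisic acid, drought and cold genes, 0.37 over 3 touch and wound genes and 0.23 over 3 auxin response genes. None of their members passed over all genes or over the list alone. GRXC9, a glutaredoxin of salicylic acid signalling, had a log2 fold change of -1.12 (adjusted p = 0.209) and was 1 of 2 measured salicylic acid genes, lower when adjusted over the list alone and, over all genes, with array weights (adjusted p over the alternatives 0.039 to 0.454). camera called 0 of the 10 lists tested at an adjusted p under 0.05 (lowest 0.248), and 1 list had an unadjusted p under 0.05. fry called 1, the flavonoid list, and without WT replicate 3 camera called 1. With F5H-OE replicate 1 left out the number of changed probe sets rose from 603 to 1758, and limma array weights, which weighted that array least, gave 2526. Left out singly, F5H-OE replicates 2 and 3 and WT replicates 2 and 3 gave 358, 237, 267 and 283, and a fit of these 2 groups alone gave 379.

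The comparison of fah-1 with WT asks what differs in stems of a line lacking F5H function. QQS, a gene found only in Arabidopsis thaliana and known to affect starch content, fell 7.18-fold, from 1772 ± 91.4 (SD, n = 3) in WT to 259 ± 110 (SD, n = 2) in fah-1 (log2 fold change -2.84, SE 0.25, adjusted p = 0.033). The probe set 253088_at, which the annotation used here pairs with no gene, fell 9.20-fold, from 2080 ± 133 (SD, n = 3) to 228 ± 42.5 (SD, n = 2, adjusted p = 6.0e-05). These 2 were the probe sets called of 22746. At an unadjusted p under 0.05 there were 1142, about the share that this threshold gives with no change at all. In simulated data of this design, limma recovered 98.0% of 4-fold, 88.6% of 2-fold and 46.3% of 1.5-fold changes in this comparison. The planted changes loosened the Benjamini-Hochberg cutoff there. With 2 calls the cutoff in the real data was stricter, so these shares overstate what it could find. The call of 253088_at held in every alternative. That of QQS ended without any 1 WT array or fah-1 replicate 2, with a robust spread and with the replicate number as a block (adjusted p 0.012 to 0.383 over the alternatives). With the block 3 probe sets were called, 2 higher and 1 lower in fah-1.

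No other named gene passed the threshold in fah-1. The named genes with the smallest p above WT, none past the threshold, were AT3G15760 with a log2 fold change of 0.58 (adjusted p = 0.463), AT5G58680 with 0.54, AT5G38290 with 0.44, AT1G52510 with 0.42 and AT3G23880 with 0.40. Those below WT were AT2G15042 with -1.10 (adjusted p = 0.281), AT5G44910 with -0.71, the anthocyanin glucosyltransferase gene UGT75C1 with -0.64 and AT1G67510 with -0.46. AT2G15042 passed in a fit of WT and fah-1 alone (adjusted p = 0.042, with 0.042 to 1.00 over the alternatives).

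Of the 61 named list genes, 0 changed in fah-1 against WT by limma, with 6 at an unadjusted p under 0.05, while camera shifted 3 lists. The 3 measured secondary wall polysaccharide genes, all of xylan synthesis, had log2 fold changes of -0.55 for IRX10, -0.46 for IRX15 and -0.34 for IRX15-L, with SEs of 0.12 to 0.16. camera placed this list lower (adjusted p = 0.00074, but adjusted p = 0.262 with an estimated correlation), and 2 of its members were lower when adjusted over the list alone. The flavonoid list was lower by camera (adjusted p = 0.029, but adjusted p = 0.262 with an estimated correlation), with UGT75C1 lower when adjusted over the list alone, 5MAT at -0.24, DFR at -0.20 and a median of -0.15. The touch and wound list was higher (adjusted p = 0.0099, but adjusted p = 0.262 with an estimated correlation), with ZAT10, a stress-responsive zinc finger gene, at 1.22, higher when adjusted over the list alone, and CML38 at 1.01. With an estimated correlation camera called 0 of the 10 lists, and fry also 0. Without WT replicate 2 or without fah-1 replicate 2, camera called 1 list in place of 3.

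REF1 had a log2 fold change of -0.31 (adjusted p = 0.951), PRX72 of 0.38 and GRXC9 of 0.73 in fah-1 against WT, none past the threshold. The photosynthetic markers had a median of 0.02. The medians of the other lists tested as sets were 0.11 for lignin polymerisation, -0.03 for sinapate esters and phenylpropanoid glucosides, -0.05 for jasmonate and ethylene defence (mean 0.00041, camera's direction upwards and fry's downwards), -0.02 for aliphatic glucosinolates, 0.10 for abscisic acid, drought and cold and 0.04 for auxin response, with no member past the threshold over all genes or over the list alone. The lists with 1 or 2 measured genes, those of the monolignol pathway, shikimate and phenylalanine, salicylic acid defence, indole glucosinolates, heat shock, circadian clock, senescence, cell cycle, phloem and flower and silique, were not tested as sets, and no member passed over all genes in any comparison. In F5H-OE against WT, WRKY6 was the 1 measured senescence gene, with a log2 fold change of 0.33 (adjusted p = 0.283). It and SWEET11 were each alone in a list, where adjustment over the list changes nothing. Both thus had only an unadjusted p under 0.05 by limma, as had 3989 of the 22746 probe sets.

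The direct comparison of F5H-OE with fah-1 tests whether the lines differed from one another. IRX10 was 1.56-fold higher in F5H-OE, at 1522 ± 144 (SD, n = 3) against 973 ± 60.7 (SD, n = 2, adjusted p = 0.038), and camera placed the 3 secondary wall polysaccharide genes higher in F5H-OE (adjusted p = 0.0058). With an estimated correlation the list had an adjusted p of 0.858, from an unadjusted p of 0.088, and fry gave an adjusted p of 0.129. IRX15-L at 0.53 and IRX15 at 0.49 (log2 fold changes) did not pass over all genes, and all 3 genes were higher when adjusted over the list alone. Over all genes both passed with array weights (adjusted p over the alternatives 0.012 to 0.602 and 0.026 to 0.570). The call of IRX10 ended in 7 of 14 alternatives (adjusted p 0.0041 to 0.330), namely with each array recentred on its median, in a fit of the 2 groups alone, with the replicate block and without F5H-OE replicate 2 or 3 or either fah-1 array.

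Between the lines, 449 probe sets changed, 259 higher and 190 lower in F5H-OE, including 238 named genes. With each array recentred on its median the split was 211 higher and 241 lower. GSTU25 was at least 20.8-fold higher in F5H-OE, with 1 of the 2 fah-1 arrays at the level of the TrpnX control probe sets. Among the named genes, further large rises were those of AT1G02300, 5.11-fold, AT3G20340, 5.05-fold, and OCT5, an organic cation transporter, 3.85-fold. AT2G07000, CYTC6A, AT5G37980, AT5G64640, AT1G70500 and AT5G48740 followed with log2 fold changes of 1.91, 1.84, 1.82, 1.75, 1.69 and 1.55. The largest falls of named genes had log2 fold changes of -3.95 for AT3G53980, -3.69 for AT5G51620, -3.17 for HRD, -2.97 for AT5G56380 and -2.81 for AT5G56910. AT5G58980, AT5G44380, AT1G06640 and AT1G19960 had log2 fold changes of -2.51, -2.47, -2.42 and -2.42, and AT3G29120, not above the TrpnX level in any F5H-OE array, was at least 3.49-fold lower. Of these 20 genes 8 lay inside the dense stretches. Without 1 of the fah-1 arrays the calls of AT1G70500, AT1G19960, HRD, OCT5 and AT3G20340 ended, with adjusted p over all alternatives of up to 0.233, 0.130, 0.071, 0.068 and 0.070. That of AT1G70500 also ended without F5H-OE replicate 2 or 3, with the replicate block and in a fit of these 2 groups alone. GRXC9 at -1.85 (adjusted p = 0.094), ZAT10 at -1.17 and SWEET11 at -1.98 did not pass, and GRXC9 and 1 touch and wound gene were lower when adjusted over the list alone. With array weights GRXC9, ZAT10 and SWEET11 passed, and without F5H-OE replicate 1 GRXC9 and SWEET11 did (adjusted p over the alternatives 0.0090 to 0.540, 0.029 to 0.647 and 0.0068 to 0.713). Median log2 fold changes were 0.12 for lignin polymerisation, -0.12 for sinapate esters and phenylpropanoid glucosides, 0.0039 for flavonoids (mean -0.07), 0.08 for jasmonate and ethylene defence, 0.02 for aliphatic glucosinolates, -0.08 for abscisic acid, drought and cold, -0.25 for touch and wound, 0.21 for auxin response and 0.02 for photosynthetic markers, with no list call by camera. The count of 449 became 92 and 69 without fah-1 replicate 1 and 2, 1554, 246 and 168 without F5H-OE replicates 1, 2 and 3, 274 with these 2 groups alone and 2878 with array weights.

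Across the 22746 probe sets, the log2 fold changes of the lines against WT had a Pearson correlation of 0.163, over genes that are not independent replicates. Unchanged groups simulated against the same WT arrays gave 0.448 (0.423 to 0.478 in 50 simulations), because the arrays of WT entered both comparisons. The covariance was 0.00788 against a simulated 0.00979, a difference of -0.0019. The simulation held no changed genes and gave all groups 1 spread per probe set, shared over the 8 arrays. Residual SDs were 0.136 to 0.156 in the WT arrays, 0.251 in F5H-OE replicate 1 and 0.087 in fah-1. The shortfall in both measures therefore cannot decide whether the effects of the lines diverge. The correlation was 0.268 without WT replicate 1, 0.093 without F5H-OE replicate 1 and 0.099 without fah-1 replicate 1. Of the called probe sets, QQS was lower in both lines, where independent lists of 310 and 2 would share 0.027, and part of such an excess may come from the shared WT arrays. QQS was 1.52 ± 0.23 (log2, SE) below WT in F5H-OE, from 1772 to 626 ± 135 (intensity, SD, n = 3), with an adjusted p of 0.013. Without WT replicate 2 or 3 or F5H-OE replicate 3 this call ended (adjusted p 0.0056 to 0.063 over the alternatives). 253088_at was called in opposite directions, where independent lists would share 0.053, at 15046 ± 369 (SD, n = 3) in F5H-OE, 7.24-fold above WT.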

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

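The comparison of the lines with one another was set before the data were seen, and 253088_at, and QQS in F5H-OE, were picked out after their values were seen. The effects of F5H-OE and fah-1 against WT differed for the probe sets called in both lines, by limma's test of the difference itself. 253088_at was 7.24-fold above WT in F5H-OE and 9.20-fold below it in fah-1, a difference of 6.06 ± 0.12 (log2, SE, adjusted p = 3.3e-07). It separated the 3 groups in all 8 arrays, with log2 intensities of 13.84 to 13.91 in F5H-OE, 10.93 to 11.11 in WT and 7.63 and 8.01 in fah-1. Its rise in F5H-OE and its fall in fah-1 went the way of the labels for F5H, although loss of function need not lower a transcript. The annotation used here pairs 253088_at with no gene, so whether it measures F5H itself could not be told. No explanation was tested. QQS lay below WT in both lines and was 1.32 ± 0.25 (log2, SE, adjusted p = 0.041) higher in F5H-OE than in fah-1. The difference ended as a call in 6 of 14 alternatives, with adjusted p of 0.013 to 0.248.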

How the results depend on the processing

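The alternatives that keep only placed genes outside the dense stretches, or leave list members inside them out, were chosen after seeing the data, and the others before. The 2-fold threshold can only lower a count. The counts outside the dense stretches are of 11466 placed genes, not of all probe sets. Of these genes the main fit called 184 in F5H-OE against WT and 140 in F5H-OE against fah-1. Most of the fall from 603 and 449 there thus came from the smaller set counted. The cause of the other changes below was not tested. In F5H-OE against WT, 603 probe sets became 379 with only these 2 groups in the fit, 2526 with array weights, 401 with the replicate block, 179 at 2-fold or more, 164 outside the dense stretches, and 237 to 1758 with 1 array left out, and 0 lists became 1 by fry and 0 to 1 with 1 array left out. In fah-1 against WT, 2 became 1 with a robust spread and 1 to 2 with 1 array left out, and 3 lists became 0 with an estimated correlation, 0 by fry and 1 to 3 with 1 array left out. In F5H-OE against fah-1, 449 became 274, 2878, 229, 167 and 126 under the first 5 of these, in that order, and 69 to 1554 with 1 array left out, and 1 list became 0 with an estimated correlation and 0 by fry. The correlation of the lines' changes was 0.0929 to 0.268 with 1 array left out. With 1 array left out, the log2 fold change of PRX71 in F5H-OE against WT was -0.051 to 1.03 and that of CML38 -0.072 to 1.52, both below 0 without F5H-OE replicate 1, and that of HCT -0.028 to 0.165, below 0 without F5H-OE replicate 3 or WT replicate 2. Of the named genes past the threshold, 4 of 24, 1 of 2 and 7 of 23 lost it in some setting in the 3 comparisons, in the order above, and the others kept it in every setting run. Of those not past it, 6 of 13, 1 of 19 and 5 of 5 gained it in some setting. Fits that leave 1 fah-1 array assume that it varies like the other groups. The alternatives for the F5H transcript were not run, because no probe set carried its name. Dim probe sets lie near background, which limits their folds.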

Other observations

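The gene families described here were chosen after the results were seen, and so were the tests of probe mismatches, of chromosome segments, of RNA degradation and of wounding, while the tests of tandem copies, of segments varying between the F5H-OE arrays and of other splits were set before their results. Among 11 measured tau-class glutathione S-transferase genes, GSTU25 and GSTU18 rose in F5H-OE against WT, GSTU18 by 0.41 ± 0.08 (log2, SE, adjusted p = 0.039). GSTU22 at 0.62 (adjusted p = 0.142) and 8 further genes did not pass. camera, over 33 families formed by symbol stem, placed the genes higher (adjusted p = 0.0049), fry also (adjusted p = 0.00025), and with an estimated correlation the adjusted p was 0.347. Without GSTU25 the median log2 fold change of the other 10 was 0.16 (limma camera, unadjusted p = 0.0053). The number of them above 0 was 8 as deposited, recentred or quantile normalized again. In F5H-OE against fah-1 the family had a median of 0.14, camera did not call it (adjusted p = 0.056) while fry did (adjusted p = 0.00062), and with an estimated correlation the adjusted p was 0.645. Without GSTU25 6 of the other 10 were above 0 (camera, unadjusted p = 0.113). In fah-1 against WT the family's median was 0.09 (camera adjusted p = 0.330).

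Genes changed in F5H-OE against WT lay close together on the chromosomes, with 7.54% changed inside the dense stretches and 1.60% elsewhere. With 1 changed gene kept per 10 neighbours the ratio of these shares was 3.32, above the 2.26 that shuffles reached, which argues against tandem copies as the whole cause. Of the changed genes inside, 56.8% were lower in F5H-OE, which argues against probe mismatches alone, since these lower a signal. Chromosome segments that differ in sequence or local expression from the WT parent may account for the pattern: in stretches picked without F5H-OE and WT replicate 1, the share of genes over 2-fold apart between those arrays was 3.21 times that elsewhere, but 1 of 10000 other sets of windows reached the same ratio, where the bound set for this test was above all of them, and its rule was revised after a first version gave no value. The ratios for replicates 2 and 3 were 2.37 and 1.46, which 20 and 367 other sets reached, so this explanation stays open, as does an effect of the F5H-OE line itself, which the design does not separate from it. For fah-1 replicates 1 and 2 against the left-out WT array, the ratios were 3.2 and 1.77 in the stretches picked without replicate 1, 0.297 and 0.416 without replicate 2, and 0.990 and 0.755 without replicate 3, each from 1 to 10 genes inside.

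F5H-OE replicate 1 stood apart from replicates 2 and 3, with a residual SD of 0.251 against at most 0.173 in the other arrays. Its GAPDH 3′ minus 5′ difference of 1.47 (others at most 0.853) and that of actin, 1.06 (others at most 0.667), were the highest, as further RNA degradation would give. That of ubiquitin, 1.08, lay within the other arrays (up to 1.16). This depends on the probe sets used. A second ubiquitin control pair read 13.31 (log2) at both ends in F5H-OE replicate 1, while its 3′ value lay below its 5′ value in every other array. The touch and wound list differed by a median of 0.501 (log2), with CML38 2.50 higher and WRKY53 at -0.40, so that handling or wounding cannot be told apart from other causes on 3 genes. Genes over 2-fold apart between replicate 1 and the others were 1.05 times as frequent inside the dense stretches as outside. This ratio cannot decide whether segments vary between the F5H-OE arrays. The stretches were picked from calls that favour genes on which all 3 of these arrays were alike. Among the genes that set the array apart, AT5G05600 was 3.79 higher and the difference was -3.22 for AT2G44260 (log2). AT5G05600 was at 9.44 in replicate 1, near the means of WT, 9.23, and fah-1, 9.32, and at 5.23 and 6.07 in replicates 2 and 3. SWEET11, AT4G24430 and AT2G14095 also lay near WT in replicate 1, while CCR2, AT1G15010 and AT4G20860 lay farthest from WT there. Replicate 1 had correlations of 0.989, 0.985 and 0.987 with WT replicates 1 to 3, and 0.985 and 0.988 with F5H-OE replicates 2 and 3. Why it was partly like WT was not tested.

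In F5H-OE against WT the real split of the 6 arrays gave 603 changed probe sets and the highest other split gave 1, with 1 of the 10 splits giving as many as the real one, which is too few splits for a share under 0.05. Of the probe sets that the annotation used here leaves unnamed, 256589_at had a log2 fold change of 3.79, 266290_at of 3.77 and 247358_at of -3.56 in F5H-OE against WT.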
